A study of Mus musculus with 4 samples.

How the data were processed

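Pre-B cells of C57BL/6J mice were profiled in 4 RNA-seq libraries, 1 for each of wild type and STAP-2 transgenic marrow at steady state and wild type and STAP-2 knockout marrow 1 month after transplantation. Per the labels' protocols, total RNA was prepared with a miRNeasy kit and libraries with a TruSeq stranded mRNA kit. Per the submitters' processing notes, mm10 was the genome build and TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 were used. The role and order of these tools, the annotation, any filter and the Cufflinks module are not given in the sources used here. The values deposited by the authors are read as FPKM, a value normalised to transcript length and library size, because they are not whole, are highest in very short genes and come with Cufflinks in the processing notes. The headers name no unit. Whether the authors scaled the libraries to each other is not given either. A length-normalised value is unstable for very short genes, and Cufflinks divides reads between overlapping or near-identical genes, so small RNA genes, histone genes, pseudogenes and close paralogs are treated as uncertain. Poly(A) selection by the kit also captures replication-dependent histone and small RNA transcripts poorly.

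Depth was recovered from the FPKM values. In genes with 1 annotated transcript, low values lay on steps of 1 read, and a length of the transcript minus 210 nt gave the largest share of 941 genes within 1% of a common depth, 49.3%. Of 6264 values of 1 to 20 estimated reads in genes with 1 annotated transcript, 67.5% came out within 0.1 of a whole read, against 20% by chance. The genes that set the depth are among them, so part of that share is built in. Relative depth came from the steps of 1041 low genes shared between libraries. The estimates were about 7320000, 7260000, 7750000 and 8680000 reads for wild type and transgenic at steady state and wild type and knockout after transplantation. These reads are approximate for genes with several transcripts and were used for intervals, for simulated noise and for the ratios of summed reads weighed in the closing section. Ratios of FPKM carry 95% exact Clopper-Pearson intervals from the estimated reads of both libraries, which cover counting error only, since reads without molecular identifiers are not independent molecules.

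Differences were taken as log2(FPKM + 1) of one library minus the other, which understates the change of low genes. They were taken among genes at 1 FPKM or more in at least 1 of both libraries, and genes were counted at 2-fold on that scale. Fold values printed with an interval are plain ratios of FPKM. No p-value is given, since each group has 1 library. The choices of comparisons, thresholds, 38 gene lists, alternatives and the rule for named genes were made before the data were examined. Each list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins with seed 1, and a list is said to stand apart at a percentile of 2.5 or less or 97.5 or more. That percentile describes these libraries and is not a p-value. Lists needed 5 measured members. Those for the mitochondrial genome and for immunoglobulin heavy and light chain segments matched none of the gene symbols and gave no value, after Ighmbp2, which is not a segment, was removed from the heavy chain pattern.

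The rule named Stap2, the 12 highest and 12 lowest genes of each comparison at 5 FPKM or more in either library (immunoglobulin and T cell receptor segments, Gm-numbered, Rik, Mir and Snor genes and bare identifiers left out). It also named up to 4 members of each list with the largest differences, and the 10 genes each that were most strongly apart in opposite and in the same direction in both genotype comparisons. Other genes were chosen after their values were seen: Slitrk6, genes named for being read in the transgenic library alone, and further list members given as examples. The second neutrophil list of the closing section was written after the neutrophil pattern was seen and before the values of its own genes were. Coordinates, lengths and GC content came from GENCODE M21 on GRCm38, the assembly that mm10 names, whose annotation may differ from the one the authors used. Of the 23284 symbols 20911 matched directly, 1915 through a synonym and 458 not at all.

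Counting noise was simulated in 100 draws of Poisson reads from the mean of both libraries. The procedure was tested on simulated reads for genes with a transcript of 300 nt or more, drawn from the wild-type library of each comparison. These reads held Poisson counting noise only and no other variation between libraries. The shares below therefore do not estimate false calls in the real libraries. For the transgenic comparison, over 10538 genes, 100% of genes raised 3-fold, 94% of genes lowered 3-fold and 98% of genes lowered 4-fold passed 2-fold, and 0.242% of unchanged genes did. For the knockout comparison, over 10613 genes, the corresponding shares were 100%, 92%, 100% and 0.144%. A list of 20 genes raised 1.5-fold reached percentile 100 in both. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, 4 other scalings, thresholds of 1.5-fold and 4-fold, and unmatched random lists. A restriction to genes with a transcript of 300 nt or more and a correction for GC content and transcript length were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.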

Results

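RNA-seq was carried out on pre-B cells, the bone marrow precursors of B lymphocytes that have assembled an immunoglobulin heavy chain, from C57BL/6J mice. There were 4 libraries, 1 in each of 4 groups. Wild-type marrow and marrow transgenic for signal-transducing adaptor protein-2 (STAP-2, gene symbol Stap2) were taken at steady state, and both libraries carry the code 0901 in their titles. Wild-type marrow and marrow labelled STAP-2 knockout were taken 1 month after transplantation, and both carry the code 0826. The study asked why B lymphopoiesis is inefficient when STAP-2 is in excess and which pathways the adaptor controls in stressed marrow. Each library gave an FPKM value for 23284 gene symbols. Of these, 10547 were at 1 FPKM or more in wild type at steady state, 10648 in the transgenic library, 10622 in wild type after transplantation and 10511 in the library labelled knockout. Depth, estimated from the steps of 1 read among low genes, was about 7320000, 7260000, 7750000 and 8680000 reads in the same order. A transcript of 1500 nt at 1 FPKM thus rested on 9.45, 9.37, 10 and 11.2 reads. With 1 library per group no difference has a replicate check, and the 95% intervals given for ratios cover counting error only.

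Stap2 itself (chromosome 17, 55997077 to 56005584, minus strand, GRCm38; 1 annotated transcript of 1509 nt) was close to the detection limit in every library. It stood at 0.212 FPKM in wild type at steady state and 0.536 in the transgenic library, which correspond to 2 and 5 reads and a ratio of 2.52 (0.413 to 26.5). After transplantation it was listed at 0 in wild type, where 3 reads would be 0.301 FPKM, and at 0.179, or 2 reads, in the library labelled knockout. Its level therefore checks neither label, and for the knockout it lies on the opposite side of its wild type. A gene-level value does not show which exons the reads cover, so reads outside a deleted part were not told apart, nor was a transgene with another sequence. Every direction given below for the library labelled knockout rests on that label. The related adaptor Stap1 was at 34.1 FPKM in wild type and 38.4 in the transgenic library at steady state, and after transplantation at 48.3 in wild type and 36.8 in the library labelled knockout.

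The comparison of transgenic with wild-type pre-B cells at steady state bears on the effect of added STAP-2 without transplantation. In the transgenic library interferon-stimulated genes, neutrophil and monocyte markers, and genes of DNA replication and mitosis were higher, and the surrogate light chain genes were several-fold higher. Erythroid, megakaryocyte and plasma cell markers, immediate early genes and B lineage transcription factors were lower. For the erythroid, megakaryocyte and plasma cell markers and the B lineage factors, transplanted wild type lay below the steady-state wild type as well, at medians of -0.97, -0.63, -0.80 and -0.15. Oas2, an antiviral oligoadenylate synthetase, was at 5.30 FPKM in wild type and 24.9 in the transgenic library, a ratio of 4.69 (3.91 to 5.65). Vpreb1, a component of the surrogate light chain, was at 7.31 and 34.4 FPKM (ratio 4.71, 3.13 to 7.18), and S100a8, an abundant neutrophil protein gene, at 293 and 720 FPKM (ratio 2.46, 2.23 to 2.71).

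Of 23 measured interferon-stimulated genes, 22 were higher in the transgenic library and 11 of them by at least 2-fold, with a median difference of 0.94 on the log2(FPKM + 1) scale (percentile 100 among 10000 random lists matched on mean expression). Beside Oas2, Ifi27l2a stood at 348 and 1163 FPKM (ratio 3.34, 3.06 to 3.66), Oas1a at 4.63 and 16.8 (3.63, 2.68 to 4.93) and Ifi44 at 0.253 and 4.13, the last resting on about 5 reads in wild type. The remaining libraries had levels near the transgenic one: Oas2 was at 25.6 FPKM in wild type after transplantation and at 27.8 in the library labelled knockout, so that the steady-state wild type was the low library of the 4. All 17 neutrophil and myeloid progenitor markers moved with these genes, at a median of 1.00 (percentile 100), 8 of them by at least 2-fold. Retnlg, a granulocyte resistin-like gene, was at 10.6 and 45.7 FPKM (ratio 4.33, 2.85 to 6.59), Lcn2 at 23.7 and 65.7 (2.77, 2.25 to 3.45) and Mmp8 at 0.972 and 4.90 (5.04, 2.88 to 9.13). Monocyte and macrophage markers had a median of 0.74, with 7 of 9 higher (percentile 100) and 0.46 without the filter for low values, among them the complement genes C1qa (ratio 7.39, 2.11 to 37.0) and C1qb (4.32, 1.93 to 12). Il1b, the gene of interleukin-1 beta, had a ratio of 7.63 (3.53 to 20.3), yet the NF-kB target list as a whole was level, at a median of 0.01 with 10 of 15 genes higher (percentile 75.8).

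Within the B lineage, Igll1 was at 14.6 FPKM in wild type and 39.9 in the transgenic library (ratio 2.73, 2.06 to 3.61), and Vpreb2 was listed at 0 and at 3.74. Dntt, the terminal transferase of early B progenitors, was at 2.12 and 7.53 FPKM (3.55, 2.35 to 5.69), and Ly6a, which encodes Sca-1 and is itself interferon-inducible, at 32.3 and 118 (3.65, 3.06 to 4.40). Here too the steady-state wild type was the low library of the 4: transplanted wild type and the library labelled knockout had Igll1 at 36.4 and 49.7 FPKM, Vpreb1 at 30.2 and 38.6, Vpreb2 at 7.59 and 8.86 and Dntt at 12.1 and 15.1. The full pre-B marker list had a median of -0.12 with 5 of 11 genes higher (percentile 6.67), with its members Rag1 (638 and 429 FPKM, ratio 0.672, 0.660 to 0.684) and Sox4 (241 and 158, ratio 0.655, 0.633 to 0.678) lower. Of 18 B lineage transcription factors 17 were lower, at a median of -0.21 (percentile 0.020), including Irf4 (259 and 173 FPKM), Foxo1 (111 and 78.2) and Ebf1 (194 and 140). All 22 DNA replication genes were higher, at a median of 0.34 (percentile 100), and so were all 21 mitosis genes, at 0.36 (percentile 100). Examples were Cdc6 (ratio 1.69, 1.39 to 2.07), Prim1 (1.60, 1.37 to 1.87) and Ube2c (1.45, 1.31 to 1.62). Higher medians were also found for heat shock proteins (0.35, 11 of 11 higher, percentile 99.98), and homing and adhesion genes (0.21, 9 of 14, percentile 99.98). The same held for immature and mature B cell markers (0.17, 15 of 16, percentile 99.9), the IL-7 receptor and STAT5 pathway (0.13, 14 of 19, percentile 99.2), ribosomal proteins (0.13, 81 of 84, percentile 100) and nuclear oxidative phosphorylation (0.10, 55 of 76, percentile 100).

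Immediate early genes had a median of -0.47, with 14 of 19 lower in the transgenic library (percentile 0). Klf4 was at 48.1 FPKM in wild type and 19.1 in the transgenic library, 2.53-fold lower (2.25 to 2.85), Klf2 at 473 and 239, and Fosb at 27.8 and 14. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, was 2.12-fold lower (1.71 to 2.62), while the ERK feedback list had a median of 0.01 (percentile 54.7). Erythroid markers were lower in 6 of 7 cases, at a median of -1.01 (percentile 0), with Hba-a1 at 32.6 and 3.89 FPKM and Slc4a1 at 1.45 and 0.190, although the globin genes have near-identical copies whose reads may have been split. The erythroid median was -0.18 when genes below 1 FPKM were kept and -0.61 among genes with a transcript of 300 nt or more, a restriction added after the data were seen. All 8 plasma cell markers were lower, at a median of -0.51 (percentile 0), with Igj at 306 and 204 FPKM. Megakaryocyte markers had a median of -0.71 with 4 of 5 lower (percentile 0.195), or -0.21 without the filter, and Ppbp, a platelet chemokine gene, was at 4.38 FPKM and, with 1 read, at 0.158, 27.8-fold lower (4.59 to 1135). Large single-gene differences outside these groups were Ctse, the gene of cathepsin E (133 and 11.1 FPKM, 12-fold lower, 10.1 to 14.3), and the ubiquitin ligase gene Mid1 (6.11-fold lower, 4.44 to 8.43). The extracellular matrix gene Reln was 3.33-fold lower (3.13 to 3.55), and so were the linker histone genes Hist1h1c (5.40-fold lower, 4.96 to 5.88) and Hist1h1d (3.65-fold lower, 2.93 to 4.55), which belong to a multigene family.

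On the other side, Prg2, which encodes the major basic protein of eosinophil granules, was at 3.46 and 35.1 FPKM (ratio 10.1, 6.02 to 18.1), and the eosinophil ribonuclease gene Ear1, which has close paralogs, was listed at 0 and at 5.45. Slitrk5, a gene of a neuronal transmembrane protein on chromosome 14 (111675097 to 111683141, plus strand), was at 0.0297 FPKM in wild type, or 1 read, and at 86.4 FPKM, or about 2901 reads, in the transgenic library (ratio 2914, 525 to 115580). It was listed at 0 in both transplant libraries. Ndufs5 (0.144 and 36.1 FPKM), Rnaset2a (0.00292 and 5.45), Hist2h4 (0.969 and 9.77) and the pseudogene Rpl34-ps1 (112 and 4.50) also ranked among the extremes. So did the small RNA genes Rnu11, Scarna3a and Scarna6, each listed at 0 in 1 of the 2 libraries. For these 7 the difference is uncertain, because reads shared with a copy or an overlapping gene, or a very short transcript, can move the estimate. Erdr1 (382 and 109 FPKM), Hbb-b2, Beta-s and the Klra1 receptor gene, a member of a multigene family, complete the 12 lowest.

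Lists whose medians lay inside the central 95% of random lists in this comparison were pre-B cell receptor signalling (-0.03), V(D)J recombination (0.02), p53 targets (0.01), pro-apoptotic BCL2 family members (-0.07), STAP binding partners (-0.02), glycolysis (0.08), and cholesterol synthesis (0.12). Inside it lay also the unfolded protein response (-0.05), replication-dependent histones (0.01), sex-linked genes (-0.08), pro-B markers (-0.10), T and NK cell markers (-0.23) and alternative fate regulators (0.18). The last median lay outside the range at 5 FPKM or more (0.31) and after a correction for GC content and transcript length (0.26) added after the data were seen. At 5 FPKM or more those of ERK feedback genes and histones were -0.51 and -0.67, outside it as well. Of the fate regulators, Cebpb, a myeloid transcription factor gene, had a ratio of 4.28 (1.95 to 10.7). Dendritic cell, mast cell and stromal markers had too few measured members, 2, 2 and 4, for a percentile, and medians of -0.02, -1.18 and 0.14. Among 10843 genes at 1 FPKM or more in either library, 132 were at least 2-fold higher and 74 at least 2-fold lower in the transgenic library. Counting noise alone gave means of 15.6 and 16.2 where 108 and 52 were observed among the 10658 genes with a known length. Rescaling each library to the same sum shifted the median of all genes to -0.13 and the split to 151 higher and 138 lower. On that scale the medians of oxidative phosphorylation, ribosomal proteins, the IL-7 receptor list, mature B cell markers and homing genes were -0.02, 0.0057, 0.01, 0.06 and 0.09. Scaling by the median of gene ratios or by the upper quartile gave 137 higher and 69 lower in each case. Rescaling without the 100 highest genes gave 134 and 73, with the median of all genes at -0.02. The sums of all genes, 518224 in wild type and 563299 in the transgenic library, include small RNA genes treated as uncertain. Mir762 was listed at 0 in wild type and at 17979 FPKM in the transgenic library, and in the other direction Mir677 at 4190 and 0.

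**Figure D1:**
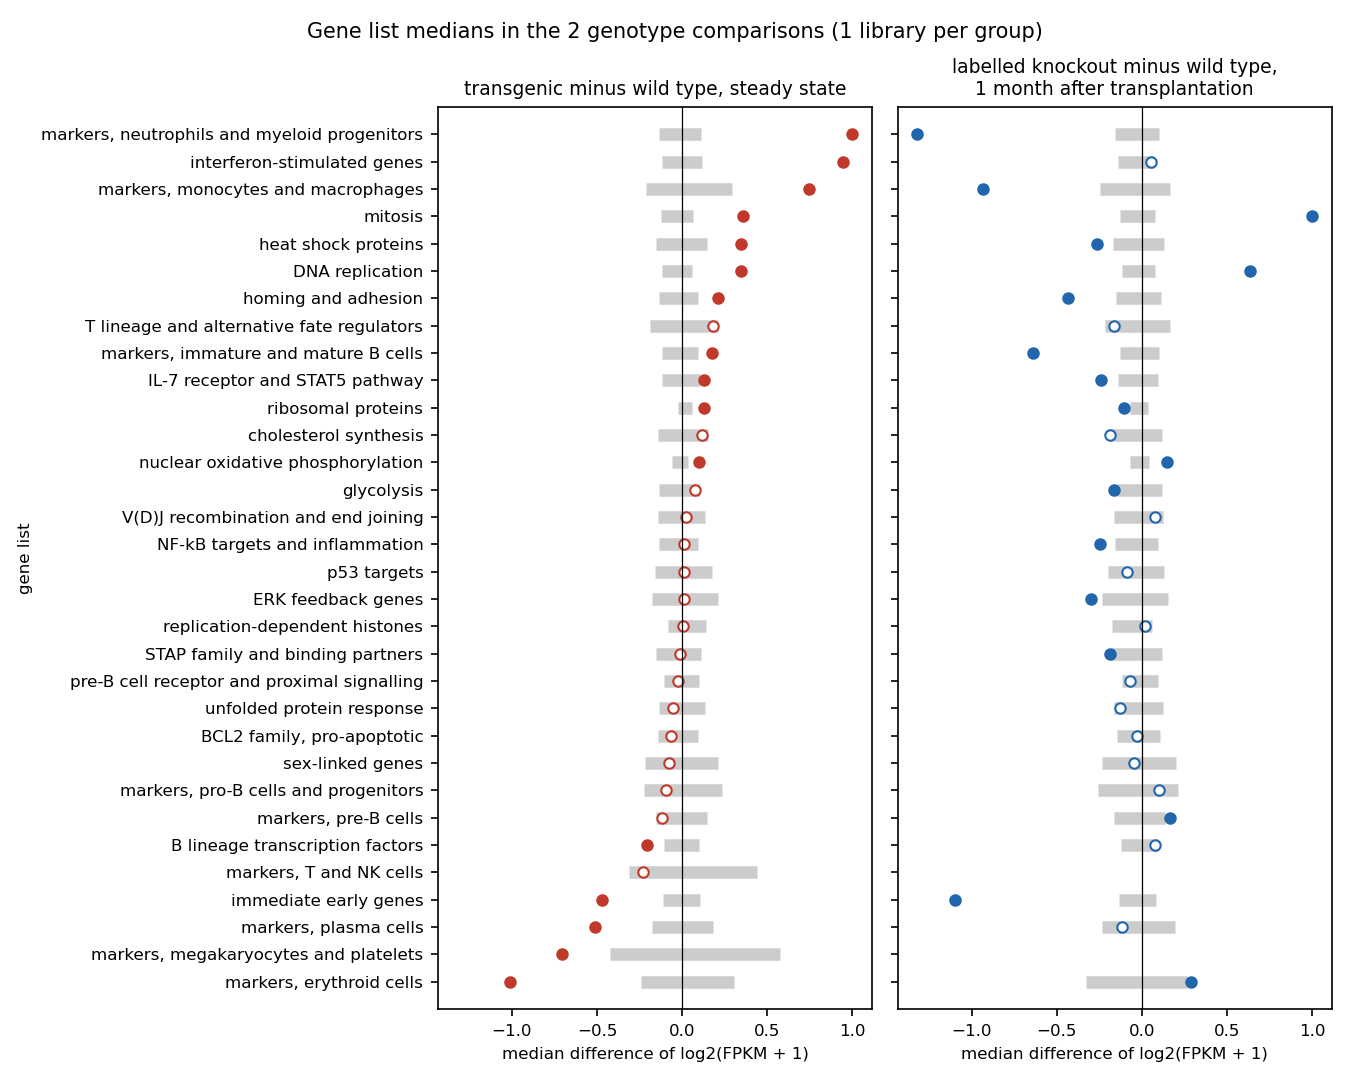
Median difference of log2(FPKM + 1) of each gene list (one line each on the vertical axis) in the transgenic comparison (left, red) and in the comparison of the library labelled knockout (right, blue), with grey bars for the central 95% of 10000 random lists and filled points for medians outside it. Neutrophil markers lie at 1.00 on the left and -1.32 on the right, and mitosis genes at 0.36 and 1.00.

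The comparison of the library labelled knockout with wild type, both 1 month after transplantation, bears on the effect of losing STAP-2 in recovering marrow. In the library labelled knockout, genes of mitosis and DNA replication were higher as a body. Immediate early genes, neutrophil and monocyte markers, and genes of maturing B cells were lower. Cdk1, the kinase that drives entry into mitosis, was at 16.5 FPKM in wild type and 37.3 in the library labelled knockout (ratio 2.26, 1.99 to 2.57), with the steady-state libraries between them at 22.8 and 28.5. Fos, an immediate early transcription factor gene, was at 334 and 102 FPKM, 3.29-fold lower (3.11 to 3.48).

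All 21 mitosis genes were higher in the library labelled knockout, 11 of them by at least 2-fold, with a median of 1.00 (percentile 100). Birc5, the gene of survivin, was at 44.3 and 97.9 FPKM (ratio 2.21, 2.01 to 2.42), Hmmr at 9.70 and 21.6 (2.23, 1.94 to 2.57) and Ube2c at 48.1 and 100.1 (2.08, 1.87 to 2.31). The kinesin gene Kif18b (2.48, 2.15 to 2.86), the cell cycle phosphatase gene Cdkn3 (2.38, 1.91 to 3.0) and the kinetochore gene Spc24 (2.36, 1.91 to 2.97) were among the 12 highest genes of all. All 22 DNA replication genes were higher as well, at a median of 0.63 (percentile 100), for example Rrm2 (87.7 and 176 FPKM, ratio 2.01, 1.88 to 2.14) and Uhrf1 (1.86, 1.76 to 1.96). Hmgb2 (196 and 371 FPKM) and Hmgb1 (340 and 526) of the V(D)J recombination list were higher too, the list as a whole having a median of 0.08 with 9 of 13 higher (percentile 90.6). Pre-B markers had a median of 0.16 with 7 of 11 higher (percentile 98.9). Igll1 had a ratio of 1.37 (1.13 to 1.66) and Vpreb1 of 1.28 (1.02 to 1.61), whereas Rag1 was at 453 and 286 FPKM (ratio 0.631, 0.619 to 0.644). Nuclear oxidative phosphorylation genes were higher at a median of 0.14, with 64 of 75 higher (percentile 100).

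All 20 immediate early genes were lower in the library labelled knockout, 12 of them by at least 2-fold, at a median of -1.10 (percentile 0). Fosb was 3.86-fold lower (3.36 to 4.43), Klf6 3.05-fold (2.79 to 3.34) and Egr1 2.71-fold (2.49 to 2.95). The 12 lowest genes also held the G protein regulator gene Rgs1 (14.6 and 1.74 FPKM, 8.37-fold lower, 6.30 to 11.3), the small GTPase gene Rhob (88.0 and 19, 4.62-fold, 4.12 to 5.21) and the stress phosphatase gene Ppp1r15a (3.75-fold, 3.41 to 4.13). The heat shock list was lower in 10 of 11 cases at a median of -0.26 (percentile 0.200), with Hspa1b 4.65-fold (4.01 to 5.41) and Hspa1a 5.22-fold (3.98 to 6.90) lower, a pair of near-identical genes whose reads may be split between them. NF-kB targets had a median of -0.25 with 14 of 16 lower (percentile 0.160). Among them the activation marker gene Cd69 was at 184 and 61.3 FPKM, 3.0-fold lower (2.70 to 3.34). ERK feedback genes had a median of -0.30 with 7 of 10 lower (percentile 0.460), or -0.17 and no longer apart from random lists without the filter for low values. The IL-7 receptor and STAT5 list had one of -0.24 with 15 of 19 lower (percentile 0.050). Myc, a member of both, was 2.21-fold lower (1.89 to 2.59), Bcl2 was at 8.64 and 4.64 FPKM and Jak3 at 20.2 and 13.5. Among the 4 members of the IL-7 receptor list that were higher was Il7r itself, at 176 and 256 FPKM, and Ccnd3 was at 166 and 225. Pmaip1, which encodes the pro-apoptotic protein Noxa, was at 16.3 and 4.85 FPKM, 3.36-fold lower (2.65 to 4.25), while p53 targets and pro-apoptotic BCL2 family members had medians of -0.09 (percentile 26.9) and -0.03 (percentile 49.6). For several of these genes transplanted wild type was the high library of the 4: wild type and transgenic at steady state had Hspa1b at 8.39 and 19.2 FPKM, against 45.2 and 9.73 in the transplanted pair, and Hspa1a, Pmaip1, Myc and Egr1 were highest there too. Fos, Fosb, Klf6 and Cd69 were also highest in transplanted wild type, and they were lowest in the library labelled knockout, with Fos at 307 and 192 FPKM at steady state.

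Markers of other cells moved with these groups. All 17 neutrophil and myeloid progenitor markers were lower in the library labelled knockout, 15 of them by at least 2-fold, at a median of -1.32 (percentile 0). Mpo was at 38.8 and 11.4 FPKM (3.41-fold lower, 2.94 to 3.97), Ctsg at 15.4 and 4.20 (3.67-fold, 2.40 to 5.77), and S100a9 at 625 and 227. The haptoglobin gene Hp, a granulocyte product outside the list, was 4.13-fold lower (2.77 to 6.31). All 12 monocyte and macrophage markers were lower, at a median of -0.93 (percentile 0), with Lyz2 at 76.2 and 27.1 FPKM (2.81-fold, 2.44 to 3.26). Of 16 immature and mature B cell markers 15 were lower, at a median of -0.64 (percentile 0), including Cd74 (2586 and 1569 FPKM), H2-Eb1 (360 and 206) and Cd40 (58.3 and 32.4, 1.80-fold, 1.58 to 2.05). Homing and adhesion genes were lower in 12 of 14 cases at a median of -0.43 (percentile 0), among them S1pr1 (1.77-fold, 1.64 to 1.92), Itgal (1.83-fold, 1.62 to 2.06) and Ccr7 (1.60-fold, 1.48 to 1.74). Erythroid markers had a median of 0.29 with 4 of 5 higher (percentile 98.2), a value that turned to -0.09 when genes below 1 FPKM were kept. Plasma cell markers had a median of -0.12 (percentile 18.6), although Igj was at 16.6 and 7.23 FPKM. T and NK cell, mast cell, dendritic, megakaryocyte and stromal markers had 4, 4, 2, 1 and 3 measured members, medians of -0.61, 0.32, -0.10, -0.63 and -0.06 and no percentile. Nkg7 was at 6.39 and 1.90 FPKM, and Fcer1a was listed at 0 and at 1.13.

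Smaller median differences outside the central 95% of random lists were found for STAP binding partners (-0.19, 9 of 10 lower, percentile 2.22), glycolysis (-0.16, 9 of 14, percentile 1.60) and ribosomal proteins (-0.11, 73 of 84, percentile 0.020). The first no longer stood apart under 5 alternatives, among them rescaling to the same sum, at -0.09. Glycolysis no longer did so at 5 FPKM or more (-0.13), against unmatched random lists or after the GC and length correction (-0.11). On the rescaled values the glycolysis and ribosomal protein medians were -0.07 and -0.0044. Inside the range lay interferon-stimulated genes (0.05, 14 of 24 higher, percentile 95.4), B lineage transcription factors (0.08), pre-B cell receptor signalling (-0.07), and cholesterol synthesis (-0.19). The unfolded protein response (-0.13), replication-dependent histones (0.02), sex-linked genes (-0.05), pro-B markers (0.10) and alternative fate regulators (-0.17) did so too. The sex-linked list holds Xist and Y-linked genes together, so its median in any comparison can hide a difference in Xist. Among 10790 genes, 72 were at least 2-fold higher and 127 at least 2-fold lower in the library labelled knockout, against means of 13.3 and 12 from counting noise where 63 and 103 were observed among 10602 genes of known length. Rescaling to the same sum changed the split to 168 higher and 159 lower, with the median of all genes at 0.06. Scaling by the median of gene ratios gave 79 and 125, by the upper quartile 82 and 125, and without the 100 highest genes 77 and 125. The last placed the median of all genes at -0.02. The sums of all genes were 557300 in wild type and 518685 in the library labelled knockout. Among small RNA genes, Mir762 was listed at 8426 FPKM and 0, and in the other direction Snord88c at 0 and 915. Rpl34-ps1, Cdk5rap1, Hist1h2bm, Atp6v0c, Rps27, Rpph1, Scarna3a and Scarna8 ranked among the 12 genes at either end and are treated as uncertain for the reasons given above. For Cdk5rap1, a protein-coding gene with a longest transcript of 2160 nt, a copy or overlap was not tested. Gsn, the gene of the actin-severing protein gelsolin, had a ratio of 2.30 (2.03 to 2.61).

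**Figure D2:**
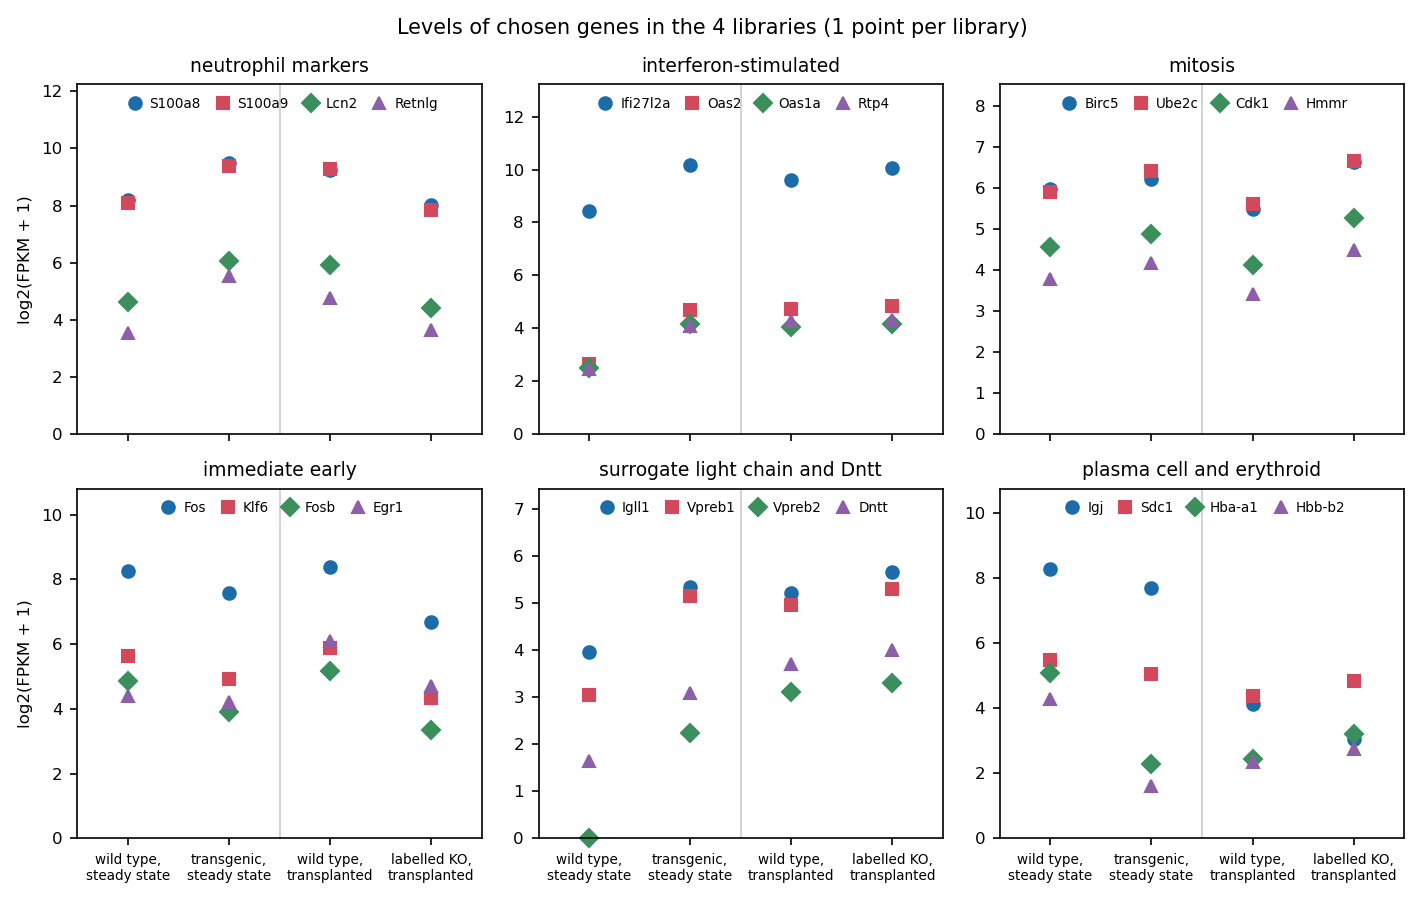
Levels of chosen genes, as log2(FPKM + 1) on the vertical axis, in the 4 libraries on the horizontal axis, with 1 point per library and gene. Neutrophil markers such as S100a8 (293, 720, 613 and 261 FPKM from left to right) are high in the inner pair of libraries, and Oas2 is low only in wild type at steady state (5.30 FPKM).

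Set against each other, these comparisons ask whether added and lost STAP-2 go with opposite differences, and they share no library. Across 11053 genes the differences had a Pearson correlation of 0.00619, with a 95% bootstrap range of about 0.207 to either side from 200 draws of genes, and a Spearman rank correlation of 0.146 (0.0199 to either side), where genes are not independent replicates. The Pearson correlation was 0.0960 over 10851 genes with a transcript of 300 nt or more, a restriction added after the data were seen. Genes at least 2-fold apart in both comparisons numbered 24 in opposite directions, where independent lists would share 2.0, and 25 in the same direction, where they would share 1.71. Under the restriction to 300 nt or more these counts were 17, against 1.34, and 18, against 1.13. Of the 24, 23 were higher in the transgenic library and lower in the library labelled knockout (1.52 for independent lists). The 10 named held the neutrophil markers S100a8, S100a9, Lcn2 and Ltf and the myeloid receptor gene Trem3 (0.347 and 4.20 FPKM at steady state, 2.95 and 0.439 after transplantation), together with Il1b and Lst1. Scarna3a and the pseudogenes Apoo-ps and Rpl34-ps1, the last with reversed signs, were the others. In the same direction went Klf4 (2.53-fold and 2.71-fold lower), Mid1 (6.11-fold and 2.91-fold lower), Aurkc, Insl3, Hist1h4k and Scarna6, all lower in the transgenic library and in the library labelled knockout. Cdk5rap1, Rps27, Hist1h3c and Rnase12 were higher in both. Insl3, Hist1h4k and Scarna6 were listed at 0 in both of these libraries, and several of the 10 rest on few reads or on copies. Insl3 also lies within the span of Jak3 on the same strand, so reads may have been divided between these genes. Mitosis genes were thus higher in both comparisons (0.36 and 1.00) and immediate early genes lower in both (-0.47 and -1.10), whereas neutrophil markers had opposite signs (1.00 and -1.32). Neutrophil markers had a median of 1.18 in transplanted over steady-state wild type, so these opposite signs also hold the gap between the wild types.

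**Figure D3:**
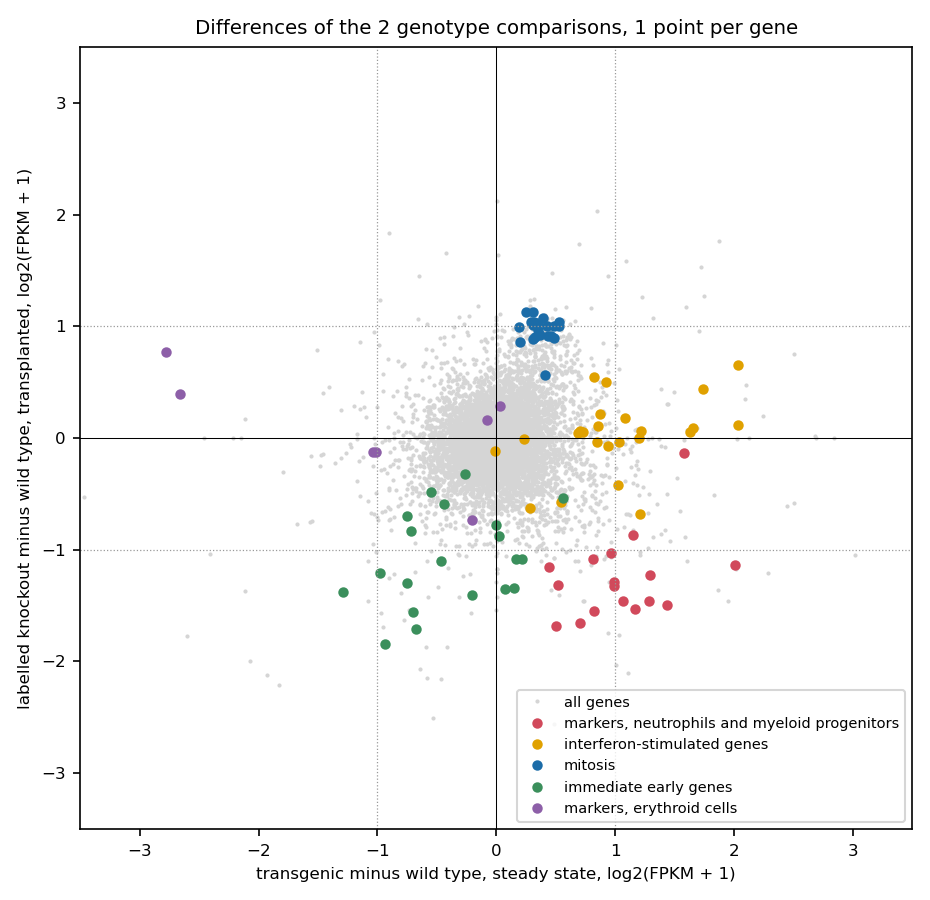
Difference of log2(FPKM + 1) between transgenic and wild type at steady state (horizontal) and between the library labelled knockout and wild type after transplantation (vertical), 1 point per gene, for 11010 genes, with 43 beyond the axes and dotted lines at 2-fold. Neutrophil markers lie at the lower right (medians 1.00 and -1.32), and mitosis genes lie above the centre (0.36 and 1.00).

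Wild-type pre-B cells 1 month after transplantation were also set against wild type at steady state, a comparison in which transplantation and the title code cannot be told apart. Interferon-stimulated genes were higher after transplantation in 24 of 24 cases at a median of 1.23 (percentile 100), as were 17 of 17 neutrophil markers (1.18, percentile 100) and 12 of 12 monocyte markers (1.03, percentile 100). Plasma cell markers were lower in 8 of 8 cases at a median of -0.80 (percentile 0), Igj, the immunoglobulin joining chain gene, being at 306 and 16.6 FPKM, 18.4-fold lower (15.7 to 21.9). Vpreb1 (ratio 4.13, 2.74 to 6.31), Dntt (5.68, 3.85 to 8.94), Ccnd2 (5.16, 3.45 to 7.94) and Ms4a1, the gene of CD20 (156 and 412 FPKM), were higher. Xist was at 78.8 FPKM in wild type and 66.0 in the transgenic library at steady state, against 34.4 in wild type and 19.4 in the library labelled knockout after transplantation. Eif2s3y, a Y-linked gene, was at 40.8, 41.0, 74.5 and 78.6 FPKM in that order. Both genes were thus read in every library, and Xist also differed within the transplanted pair. The sex and number of the animals are not given in the sources used here.

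Heat shock proteins (0.67), mature B cell markers (0.56), sex-linked genes (0.52), immediate early genes (0.39), alternative fate regulators (0.37), and the IL-7 receptor and STAT5 list (0.26) had higher medians outside the central 95% of random lists. So did glycolysis (0.25), NF-kB targets (0.25), cholesterol synthesis (0.19), the unfolded protein response (0.16), homing genes (0.14) and ribosomal proteins (0.11). Lower ones were found for erythroid (-0.97) and megakaryocyte markers (-0.63), replication-dependent histones (-0.49), mitosis (-0.30), pre-B markers (-0.25), V(D)J recombination (-0.22) and B lineage transcription factors (-0.15). The histone median was -0.06 without the filter for low values, and those of cholesterol synthesis and the unfolded protein response were 0.15 and 0.14 after the GC and length correction, none of them apart from random lists. Cxcl12, a stromal chemokine gene, was at 4.26 and 0.348 FPKM, and Slpi at 36.1 and 4.44. In all, 181 genes were at least 2-fold higher and 68 at least 2-fold lower among 10835, and 195 and 123 after rescaling to the same sum, which moved the median of all genes to -0.12. On that scale the medians of glycolysis, NF-kB targets, cholesterol synthesis, the unfolded protein response, homing genes and ribosomal proteins were 0.16, 0.15, 0.11, 0.07, 0.05 and 0.01. Scaling by the median of gene ratios gave 186 higher and 66 lower, by the upper quartile 179 and 68, and without the 100 highest genes 180 and 68. The last placed the median of all genes at -0.03.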

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

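Of the tests below, those that rest on erythroid markers and on summed marker reads were chosen only after the result was seen.

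Several gene lists stood apart in one direction in the transgenic comparison and in the other in the comparison of the library labelled knockout. With 1 library per group, none of these differences between comparisons was tested. The transgenic median minus the median of the library labelled knockout was 2.31 for neutrophil and myeloid progenitor markers, 1.68 for monocyte and macrophage markers and 0.81 for immature and mature B cell markers. It was 0.65 for homing and adhesion genes, 0.61 for heat shock proteins, 0.37 for the IL-7 receptor and STAT5 pathway and 0.23 for ribosomal proteins. These values also hold the gap between the wild types, in which transplantation and the title code cannot be told apart. Transplanted minus steady-state wild type had a median on the transgenic side for each of these lists. It was 1.18 for neutrophil, 1.03 for monocyte and 0.56 for mature B cell markers. For homing genes, heat shock proteins, the IL-7 receptor list and ribosomal proteins it was 0.14, 0.67, 0.26 and 0.11. After rescaling to the same sum, the ribosomal protein medians were 0.0057 in the transgenic comparison and -0.0044 in that of the library labelled knockout. The IL-7 receptor medians were 0.01 and -0.14. That rescaling, whose sums include uncertain small RNA genes, moved the median of all genes to -0.13 and 0.06. Rescaling without the 100 highest genes left the median of all genes at -0.02 in both comparisons. After rescaling to the same sum, both lists still stood apart from random lists on the same sides. The size of these medians thus depends on the scaling. The side of both lists among random lists could hardly change, since a single factor per library shifts list members and random genes nearly alike. The transgenic median minus that of the library labelled knockout had the opposite sign for erythroid markers, at -1.30, and their side in the transplanted pair depends on the filter for low values. For these markers too, transplanted minus steady-state wild type lay on the transgenic side, at -0.97.

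The neutrophil pattern was the widest, with 17 of 17 markers higher in the transgenic library and 17 of 17 lower in the library labelled knockout, and S100a8 at 720 FPKM and Ngp at 140 FPKM in the former. The tables argue against counting error, the ratio of summed marker reads having a lower bound of 2.16. They also argue against a lower B lineage share that raises every other cell type alike, the erythroid median being -1.01, or -0.18 with low values kept. That median was known when the test was chosen, and transplanted over steady-state wild type had an erythroid median of -0.97 as well. Monocyte markers were higher, at 0.74, so a lower B lineage share that raises only some cell types was not weighed. Neutrophils and their precursors among the sorted cells may be the source, as no sorting gate is given in the labels. Of a second list of neutrophil genes, written after the pattern was seen but before their own values were, and sharing 0 genes with the first, 12 of 16 measured members, or 75%, were higher in the transgenic library and lower in the library labelled knockout (all but Cxcr2, Itgam, Mgst1 and Padi4), with medians of 0.77 and -0.61 (percentiles 100 and 0), and of 0.83 in transplanted over steady-state wild type. That share lies between the 80% set with that list for this explanation and the 50% set against it, so this source cannot be told apart from a change within the pre-B cells, and an effect of the genotypes on myeloid cells in the marrow stays open and was not tested.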

How the results depend on the processing

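Of the alternatives reported here, the restriction to transcripts of 300 nt or more and the correction for GC content and length were chosen only after the results were seen. No paired analysis was possible because each group has 1 library. Of the values compared with an alternative, 592 medians of lists that stood apart kept their direction and side, 14 no longer stood apart and 2 changed sign. The 4 other scalings shift list members and random genes nearly alike, so they could change few sides. For lists that did not stand apart, 412 medians stayed so, 11 came to stand apart in the same direction and 2 with the opposite sign. For named genes, 496 differences moved by less than their counting error and 32 by more or had no such error, none changing sign. The cause of a changed value was not tested except where the setting itself sets it, as the threshold and the pseudocount do. Counts of genes at least 2-fold higher and lower follow in the order transgenic, labelled knockout and transplanted wild type, then genes in opposite directions. With a pseudocount of 0.1 they were 275 and 159, 154 and 267, 346 and 158, and 92, and with 5 they were 46 and 30, 18 and 51, 65 and 27, and 11. At 1.5-fold they were 413 and 251, 406 and 474, 563 and 247, and 115, and at 4-fold 35 and 25, 10 and 23, 29 and 21, and 5. At 5 FPKM or more, 69 and 44 genes remained for the transgenic comparison, 80 lower for the library labelled knockout and 41 lower for transplanted wild type. Rescaling to the same sum gave 138 lower for the transgenic library, 168 higher for the library labelled knockout and 123 lower for transplanted wild type. The rank correlation was 0.11 without a filter and 0.19 at 5 FPKM.

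In the comparison of the library labelled knockout, the erythroid median turned to -0.087 without a filter and no longer stood apart with a pseudocount of 0.1 (0.31). STAP binding partners no longer stood apart with a pseudocount of 0.1 (-0.19), without a filter or at 5 FPKM (-0.18 in both), after rescaling (-0.087) or against unmatched random lists (-0.19). Glycolysis did so at 5 FPKM (-0.13), against unmatched lists (-0.16) and after the GC and length correction (-0.11), and ERK feedback genes without a filter (-0.17). The oxidative phosphorylation median of the transgenic comparison turned to -0.022 after rescaling, which moved the median of all genes to -0.13. In transplanted against steady-state wild type, the unfolded protein response no longer stood apart with a pseudocount of 5 (0.093) or after the correction (0.14), cholesterol synthesis after the correction (0.15) and histones without a filter (-0.061). Of the lists that came to stand apart in the transgenic comparison, alternative fate regulators did so with a pseudocount of 5 (0.15), at 5 FPKM (0.31), against unmatched lists (0.18) and after the correction (0.26). T and NK cell markers did so without a filter (-0.16) and against unmatched lists (-0.23), glycolysis (0.11) and pre-B markers (-0.19) at 5 FPKM, and cholesterol synthesis against unmatched lists (0.12). The 2 with the opposite sign were ERK feedback genes (-0.51) and histones (-0.67), both at 5 FPKM. Elsewhere these were pro-B markers of transplanted over steady-state wild type at 5 FPKM (0.32) and cholesterol synthesis of the library labelled knockout against unmatched lists (-0.19). At 1 FPKM a transcript of 1500 nt rests on 9.37 to 11.2 reads, and below it on fewer, which limits what these libraries can show.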

Other observations

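Of the tests below, those of the surrogate light chain reads and of the genes near Slitrk5 were chosen only after the results were seen. The correction for GC content and transcript length used below was likewise added after the data were seen.

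Every pair of the 4 libraries differed by a similar number of genes: from 185 genes at least 2-fold apart between the library labelled knockout and the transgenic library to 249 between the wild types, with 206 and 199 in the genotype comparisons. Neutrophil markers had a median of -0.10 between transplanted wild type and the transgenic library and of -0.20 between the library labelled knockout and steady-state wild type. Their level was thus close in the transgenic library and transplanted wild type, and close in the library labelled knockout and steady-state wild type. Interferon-stimulated genes instead had medians of 0.21 and 0.22 in transplanted wild type and in the library labelled knockout over the transgenic library, and of 1.33 in the library labelled knockout over steady-state wild type. Sex-linked genes, Igj and Cxcl12 followed the title codes. Cxcl12 was at 4.26 and 7.65 FPKM in wild type and transgenic at steady state and at 0.348 and 0.155 in wild type and the library labelled knockout after transplantation.

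Mitosis and replication genes were higher in the library labelled knockout, with all 21 and all 22 measured members on that side. GC content or transcript length as the cause is argued against, since the mitosis median was 1.02 after correction for both. A larger share of large, cycling pre-B cells is a candidate explanation, as the summed reads of the surrogate light chain genes Igll1, Vpreb1 and Vpreb2, which such cells express, had a ratio of 1.32 (1.15 to 1.51) to wild type. The same ratio was 3.46 in the transgenic comparison, where the mitosis median was 0.36, and 3.28 in transplanted over steady-state wild type, where it was -0.30; these genes thus did not follow mitosis across the comparisons and weigh little for that explanation. A direct effect of genotype on the cell cycle stays open and was not tested.

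Slitrk6, singled out after its values were seen, lies 920 kb from Slitrk5 on chromosome 14 (110748580 to 110755149) and was listed at 0 in steady-state wild type, at 3.07 FPKM or about 90 reads in the transgenic library and at 1 read in each transplant library. Reads shared by sequence identity are argued against, because the transcripts have 0 31-mers in common. Of 7 genes seen in the transgenic library alone (3 FPKM or more, against 0.3 or less elsewhere), 1 besides Slitrk5 lay within 2 Mb of it. That gene was Slitrk6 itself, whose values prompted the test, and no further gene of known location lay in that window. Symbols without a known location could not be placed. The remaining 5, named after their values were seen, were Akr1b3, Ear1, Gm20571, Ndufs5 and Rnaset2a. The count therefore repeats what was seen and does not weigh for a local event on chromosome 14 in the transgenic library, such as insertion of the transgene nearby, which may be the reason but cannot be told apart from separate causes of the 2 readings.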
